A study of Homo sapiens with 6 samples.

How the data were processed

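Expression was measured on Affymetrix 3' arrays in ARPE-19 cells, an established human cell line derived from retinal pigment epithelium. Per the labels, 3 arrays came from cells given the solvent (0.1% DMSO) and 3 from cells given SRPIN803 at 10 µM, each for 4 h. The medium held 10% serum, and biotinylated RNA was made from 100 ng of total RNA with a 3' labelling kit. The group of each array came from its agent label and the replicate number from its title. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

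The values deposited by the authors are on a log2 scale, 1 value per probe set and array, and were made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of each probe set. Its software, version and options are not given in the sources used here. The deposited log2 values were used as they stand, with no floor and no further normalization. The sorted values of the 6 arrays differed by at most 0.14 on the log2 scale, as after quantile normalization, which hides any change in total RNA per cell. Changes of dim probe sets are compressed in RMA values, apart from that step. Arrays give no read depth, and their number, 3 per group, limits the precision.

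The table held 54675 probe sets, of which 62 were controls. Gene names came from the platform's annotation, where 41091 probe sets named 1 gene, 1801 named several and 11721 are unnamed here. Of the probe sets naming 1 gene, 41037 had their gene found in the reference gene table (no symbol changed) and 54 kept the array's name. No coordinates were used. Each of 19775 genes was represented by its brightest probe set over all 6 arrays, among those naming that gene alone. Some members of the gene lists have no probe set of their own here and were not analysed.

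Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 4 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Errors beside log2 changes are limma's standard errors, and ranges beside folds are 95% confidence intervals. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so no single-gene permutation test was used. The 38 gene lists, 5 of them cell type markers, were written from textbook knowledge before the data were examined, as were the main tests and most alternatives. They were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, with adjustment over the lists. An estimated correlation per list and limma's fry, which asks whether a list's genes move on balance one way, were alternatives. With an estimated correlation camera also takes the 4 residual degrees of freedom, so its p rises even where that correlation is low. Genes whose probe sets moved apart were found with limma's diffSplice (Simes test) on probe sets at or above the median level of 5.26, without those ending in _x_at, in genes with at least 2 such probe sets.

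Genes were named by a rule fixed before the data were examined. It took the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap and whose higher group lay above the median level. It added up to 4 called members of each list with the largest change, or up to 2 members with the smallest p where none was called. VEGFA, SRPK1, SRPK2, CSNK2A1, CSNK2A2 and CSNK2B were always named, and so were the 6 genes with the smallest p in the probe set test. Genes named outside this rule are marked as such.

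The tests were run on simulated data with the real levels and limma's moderated spreads, drawn independently for each gene and array. Effects shared across an array were not simulated, so real error rates may be higher. The gene test recovered 84% of genes changed by a log2 of 0.5 and 98% of those changed by 1, among 200 changed genes of 19775, and 3.70% of its calls were false. It called 0 genes when nothing was changed. For the lists, camera called the 1 list that was shifted by 0.3 and 0 others, with genes simulated as independent, which real genes are not. The probe set test recovered 81% of genes with 1 probe set moved by 0.5 and 99% with 1 moved by 1, among 200 of 5535 genes. Of its calls 12.2% were false, above the nominal level, and it called 2 genes when nothing was changed.

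Alternatives covered the replicate number as a block, each array left out in turn, filters on dim genes, the probe set chosen per gene, 3 other normalizations, the variance model, array weights, thresholds and the kind of set test. A covariate for the 5' to 3' signal of the actin control probe sets was added after seeing the data. Random draws used fixed seeds, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.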

Results

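The data comprised 6 arrays of ARPE-19 cells, a human retinal pigment epithelium line, 3 treated with solvent (DMSO) and 3 with SRPIN803 at 10 µM for 4 h. SRPIN803 is known as an inhibitor of SRPK1, a kinase of SR splicing factors, and of protein kinase CK2. The comparison asks which transcripts differ after a short exposure to the compound. Array medians lay between 5.25 and 5.28 on the log2 scale. Pearson correlations across probe sets were 0.9957 to 0.9977 within groups and 0.9940 to 0.9961 between groups, so the ranges overlapped. The lowest value within groups was between SRPIN803 replicates 1 and 2, and the lowest between groups was also with SRPIN803 replicate 2. No pair of arrays held identical values throughout, and each was counted as 1 replicate. The 5' to 3' difference of the actin control probe sets, a sign of RNA and labelling quality, was -1.77 ± 0.31 in DMSO and -1.76 ± 0.36 in SRPIN803 (log2, SD, n = 3 each).

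SRPIN803 raised SLC16A14, an orphan member of the monocarboxylate transporter family, 10.4-fold (8.32 to 13.0) and PDK4, a kinase that restrains pyruvate oxidation, 8.81-fold (6.97 to 11.1). The arrestin-family genes TXNIP, which limits glucose uptake, and ARRDC3 rose 7.16-fold (6.31 to 8.11) and 4.46-fold (4.02 to 4.96). GPCPD1 rose by a log2 of 1.83 ± 0.08, ZNF844 by 1.77 ± 0.17, VMP1 by 1.75 ± 0.11 and ANGPTL4 by 1.55 ± 0.11. The largest falls were in CXCL8, the neutrophil chemokine interleukin-8, at -2.18 ± 0.14, and PTX3, a secreted pattern recognition molecule, at -2.02 ± 0.09. RUSC1-AS1 (-1.33 ± 0.18), the sterol enzyme gene HMGCS1 (-1.23 ± 0.07), haem oxygenase HMOX1 (-1.15 ± 0.09), endothelial lipase LIPG (-1.12 ± 0.07), the ribosome assembly gene RRS1 (-1.08 ± 0.06) and hexokinase HK2 (-1.04 ± 0.08) followed. Among these 16 genes limma's adjusted p ran from 1.53e-05 for TXNIP to 0.00864 for RUSC1-AS1, and all stayed called with any 1 array left out. The 2 other probe sets of TXNIP, both above the median level, changed by 1.79 ± 0.10 and 1.65 ± 0.25, apart from the main one (adjusted p = 0.0203), and that of HMGCS1 by -0.59 ± 0.14, not called over all probe sets (0.0836). The 2 other probe sets of PDK4 and the other one of ZNF844 lay below the median level, with log2 changes down to 0.23 and 0.18.

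Over all 19775 genes, 1154 were called (5.84%), 685 higher and 469 lower after SRPIN803. Their median log2 change was 0.42 for the higher and -0.40 for the lower genes. A fold of at least 1.5 was reached by 229 genes (148 higher, 81 lower) and a fold of at least 2 by 37 (28 higher, 9 lower). The groups did not overlap in any of the 1154 called genes, and they did not overlap in 25.6% of all genes, where chance gives 10%. The count depended on each array. It was 459, 404 and 324 without DMSO replicate 1, 2 and 3, and 687, 660 and 533 without SRPIN803 replicate 1, 2 and 3.

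**Figure D1:**
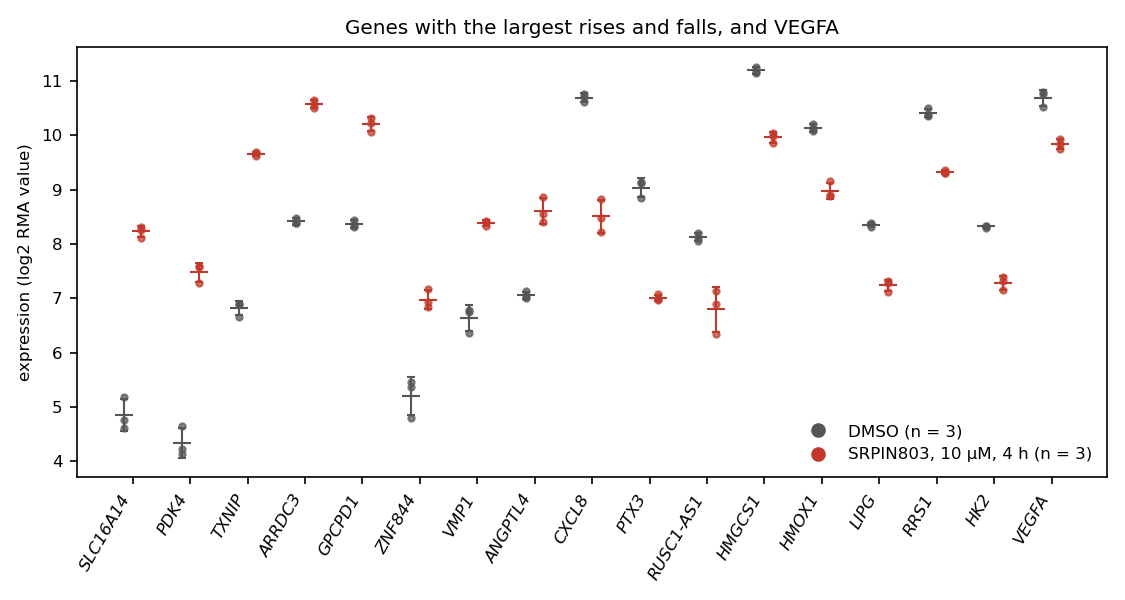
Log2 RMA expression of the 8 genes with the largest rise, the 8 with the largest fall and VEGFA, with a point per array and the mean ± SD of each group (n = 3). In each gene the DMSO and SRPIN803 arrays do not overlap, from SLC16A14 at 4.85 against 8.23 to VEGFA at 10.69 against 9.84.

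VEGFA, the main vascular growth factor, fell 1.81-fold (1.56 to 2.09), from 10.69 ± 0.15 in DMSO to 9.84 ± 0.09 in SRPIN803 (log2, SD, n = 3), with limma's adjusted p = 0.00372. Its log2 change was -0.85 ± 0.09, every SRPIN803 array lay below every DMSO array, and all 4 of its probe sets had lower means, by log2 changes of -0.85 to -0.36. VEGFA stayed called with any 1 array left out, with log2 changes of -0.94 to -0.80. Splice forms of VEGFA were not analysed here. In the list of VEGF family and angiogenic factors, 6 of 24 genes fell and 2 rose (7 and 3 adjusted over the list alone). The growth factor HBEGF changed by -0.77 ± 0.11 and the protease ADAMTS1 by -0.71 ± 0.08, while ANGPTL4 was among the largest rises. As a list these genes did not pass camera (adjusted p = 0.0572, 0.564 with an estimated correlation), but they did without DMSO replicate 1 (adjusted p = 0.0227).

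Transcripts of the compound's known targets, SRPK1 and CK2, and of SRPK2 showed no change past the threshold. Log2 changes were 0.02 ± 0.07 for SRPK1, 0.03 ± 0.08 for SRPK2, 0.02 ± 0.05 for the CK2 subunit gene CSNK2A1, -0.02 ± 0.07 for CSNK2A2 and 0.0034 ± 0.057 for CSNK2B, with adjusted p from 0.882 to 0.984. The 95% intervals of all 5 lay between -0.18 and 0.22, and the sign of each depended on the setting. These are the brightest probe sets. Another of CSNK2A1, at a level of 8.16, was at -0.33 (-0.18 without SRPIN803 replicate 2) and was not called over all probe sets. Among SRPK and CLK kinases 1 of 14 was called, CLK4, at 0.36 ± 0.08 (2 higher and 1 lower adjusted over the list alone). Its other probe set above the median level was at 0.41 ± 0.08 (adjusted p = 0.0458 over all probe sets), and of the 2 dim ones the lower was at -0.56 ± 0.28 (-0.25 without SRPIN803 replicate 2). CLK4 lost the call (adjusted p up to 0.173) without DMSO replicate 1 or 3 or any SRPIN803 replicate. The kinase list did not shift (adjusted p = 0.981), nor did the CK2 subunits (0 of 3 called, also over the list alone, adjusted p = 0.981), whose median and mean were above 0 and whose test direction was down.

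SR proteins and SR-like splicing factors, the substrates that SRPK kinases phosphorylate, were lower as a list at camera's preset correlation of 0.01. They were not with an estimated correlation. It was 0.020, close to the preset one, so the fewer degrees of freedom of that setting weigh in the loss. Of 27 genes 7 fell and 1 rose (12 and 4 adjusted over the list alone), with a median log2 change of -0.12 and camera's adjusted p = 9.94e-05, or adjusted p = 0.209 with an estimated correlation. SRSF7 changed by -0.39 ± 0.06, RBM25 by -0.37 ± 0.07 and SON by -0.37 ± 0.07, while PNISR rose by 0.38 ± 0.08. On these brightest probe sets the changes were small, and each of the 4 lost its call in 3 to 5 of the 6 fits with 1 array left out, with adjusted p up to 0.128. The arrays concerned were DMSO replicate 1 and 2 and SRPIN803 replicate 3 for SRSF7, DMSO replicate 2 and 3 and SRPIN803 replicate 1 and 2 for SON, and all but SRPIN803 replicate 1 for RBM25 and PNISR. Probe sets of PNISR ranged from -0.30 to 0.38 (-0.15 to 0.40 without SRPIN803 replicate 2) and those of SRSF7 from -0.41 to 0.18. Those of RBM25 ranged from -0.69 to -0.10 (-0.53 to -0.15 without SRPIN803 replicate 2), with 3 of 7 called lower over all probe sets. Those of SON ranged from -0.97 to -0.35 (-0.54 to -0.33 without that array), with 0 of 5 called. Among hnRNP proteins 1 of 19 was called, HNRNPA0 at -0.30 ± 0.06 (1 over the list alone), which lost the call with any 1 array left out (adjusted p up to 0.122). That list did not pass (adjusted p = 0.243).

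Camera called 8 of the 38 lists, 6 lower and 2 higher, and 2 of them, both lower, with an estimated correlation. The latter setting also has only 4 degrees of freedom, so calls lost with it cannot be laid to correlation between genes alone. Both lists that held under either setting were biosynthetic. Among MYC targets and ribosome biogenesis genes 10 of 23 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.33 (adjusted p = 1.89e-12, and adjusted p = 0.0300 with an estimated correlation). RRS1 was joined by NOP16 (-0.83 ± 0.06), the nucleolar helicase DDX21 (-0.65 ± 0.06) and the rRNA methyltransferase NOP2 (-0.58 ± 0.08). Among cholesterol synthesis genes and SREBP2 targets 8 of 19 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.23 (adjusted p = 3.86e-12, and adjusted p = 0.0300 with an estimated correlation). HMGCS1 was joined by the squalene epoxidase gene SQLE (-0.63 ± 0.07), the sterol sensor partner INSIG1 (-0.58 ± 0.08) and MSMO1 (-0.51 ± 0.06). Of these 8 genes, 7 stayed called with any 1 array left out, and INSIG1 lost the call without DMSO replicate 3 (adjusted p = 0.0518). Cytoplasmic ribosomal protein genes did not move with the ribosome biogenesis genes past the threshold (0 of 20 called, also over the list alone, adjusted p = 0.981, RPS3 at 0.03 ± 0.06 and RPLP1 at 0.02 ± 0.05). Their median and mean were above 0 and their test direction was down.

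**Figure D2:**
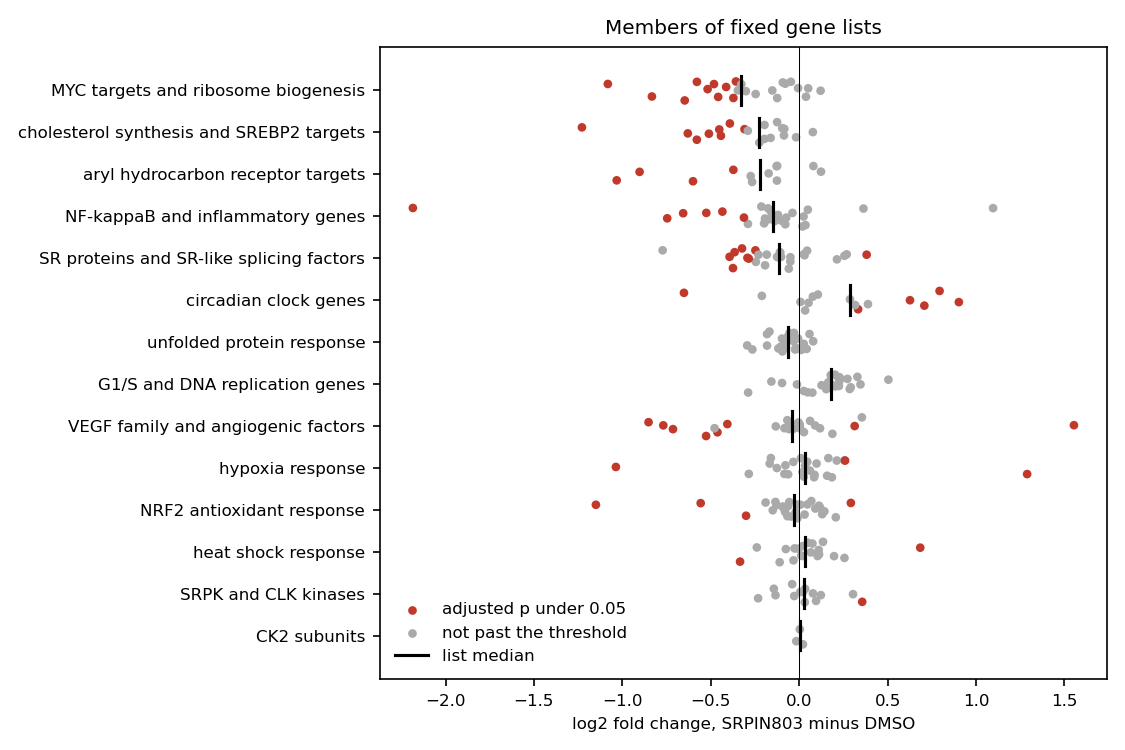
Log2 fold changes (SRPIN803 minus DMSO, n = 3 each) of the measured members of 14 fixed gene lists, the 8 called by camera at the top, with a point per gene, red where the adjusted p is under 0.05, and a bar at the list's median. Ribosome biogenesis genes have a median of -0.33 and cholesterol synthesis genes of -0.23, while CK2 subunits lie at 0.

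An inflammatory and a xenobiotic response list were lower at camera's preset correlation and not at an estimated one. In the NF-kappaB list 6 of 26 genes fell and 0 rose (6 and 2 adjusted over the list alone), with a median of -0.15 (adjusted p = 1.81e-05, or adjusted p = 0.252 with an estimated correlation). Beside CXCL8, the chemokine gene CXCL1 changed by -0.75 ± 0.09, the inhibitor gene NFKBIA by -0.66 ± 0.09 and CCL2 by -0.53 ± 0.11. Among aryl hydrocarbon receptor targets 4 of 12 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.22 (adjusted p = 1.53e-05, or adjusted p = 0.252 with an estimated correlation). The cytochrome P450 genes CYP1A1 and CYP1B1 changed by -1.03 ± 0.08 and -0.60 ± 0.07, the receptor's repressor AHRR by -0.90 ± 0.13 and the amino acid transporter gene SLC7A5 by -0.37 ± 0.08. CCL2 lost its call in all fits with 1 array left out except that without DMSO replicate 1 (adjusted p up to 0.102), AHRR without DMSO replicate 2 or 3 (up to 0.0553) and SLC7A5 in all but that without SRPIN803 replicate 2 (up to 0.163).

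Other signal-responsive lists held members that moved without a shift of the list. Of 35 immediate early genes 3 fell and 0 rose (8 and 5 adjusted over the list alone), EGR1 by -0.82 ± 0.14, KLF6 by -0.61 ± 0.06 and JUN by -0.32 ± 0.07 (list adjusted p = 0.418, median 0.01, mean -0.02, test direction down). Of 28 NRF2 antioxidant genes 3 fell and 1 rose (3 and 1 adjusted over the list alone). The cystine transporter gene SLC7A11 changed by -0.56 ± 0.09 and the glutathione synthesis genes GCLM and GCLC by -0.30 ± 0.06 and 0.29 ± 0.06 (list adjusted p = 0.173). Of 24 interferon-stimulated genes IFIT3 fell, at -0.50 ± 0.07, and IFI44 and IFIT1 rose by 0.44 ± 0.07 and 0.33 ± 0.07 (1 lower and 4 higher adjusted over the list alone, list adjusted p = 0.981, median and mean above 0, test direction down). KLF6 stayed called with any 1 array left out. EGR1 and SLC7A11 lost the call without DMSO replicate 2 or 3, IFI44 without DMSO replicate 1 or 3, and IFIT3 without DMSO replicate 3 (adjusted p up to 0.0819). IFIT1 lost it in all such fits but that without SRPIN803 replicate 1 (up to 0.148), and JUN, GCLM and GCLC in all 6 (up to 0.131). Of the 4 JUN probe sets, all lower, 2 were called over all probe sets. Those at -0.61 and -0.57, dimmer than the main one, stayed between -0.67 and -0.52 with any 1 array left out, and the dimmest was at -0.32.

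Circadian clock genes were higher as a list at camera's preset correlation of 0.01 and not with an estimated one. The estimate was 0.014, close to the preset one, so the fewer degrees of freedom of that setting weigh in the loss. Of 15 genes 5 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.010, or adjusted p = 0.252 with an estimated correlation). The PAR bZIP factor gene TEF changed by 0.90 ± 0.15, the repressor genes PER2 and NR1D2 by 0.79 ± 0.10 and 0.71 ± 0.08, and the activator gene BMAL1 by -0.65 ± 0.11. TEF lost the call in 4 of the fits with 1 array left out (without DMSO replicate 2 or 3 or SRPIN803 replicate 1 or 3, adjusted p up to 0.0776) and BMAL1 in 3 (without DMSO replicate 2 or 3 or SRPIN803 replicate 3, up to 0.0744). The other probe set of NR1D2 was at 0.18 ± 0.24 (0.50 without SRPIN803 replicate 2, whose value was low), and NR1D2 and TEF were not called with the mean of all probe sets. The list was not called among genes above the 75th percentile level (adjusted p = 0.229).

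Metabolic lists moved in part. Among liver X receptor and fatty acid genes 4 of 17 rose and 0 fell (4 and 2 adjusted over the list alone). PDK4 and ANGPTL4 were joined by the cholesterol exporter gene ABCA1 (0.58 ± 0.07) and the lipid droplet gene PLIN2 (0.51 ± 0.06), all of which stayed called with any 1 array left out. The list's median was -0.04, its mean 0.31 and its test direction up (adjusted p = 0.550). Of 25 hypoxia response genes 2 rose and 1 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.970). The peptide hormone gene ADM rose by 1.29 ± 0.08, MXI1 rose by 0.26 ± 0.06 and HK2 was among the largest falls. MXI1 lost the call with any 1 array left out (adjusted p up to 0.126). HK2 was also the 1 of 20 glycolysis genes called, over the list alone too (list adjusted p = 0.970, median 0.02, mean -0.03, test direction down). Of 23 oxidative phosphorylation genes 0 were called, also over the list alone (adjusted p = 0.651), with SDHA at -0.16 ± 0.07 and SDHC at 0.09 ± 0.07.

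Stress lists gave small or mixed changes. The unfolded protein response list was lower by camera (median -0.06, adjusted p = 0.0258) with 0 of 23 genes called, also over the list alone. That call was lost with an estimated correlation (adjusted p = 0.979) and without DMSO replicate 3 (0.0995), SRPIN803 replicate 1 (0.0712) or SRPIN803 replicate 3 (0.133). XBP1 was at -0.29 ± 0.08 and SDF2L1 at -0.26 ± 0.08. Among integrated stress response and amino acid genes 1 of 28 rose and 2 fell (1 and 2 adjusted over the list alone, list adjusted p = 0.651). SLC38A2 changed by 0.85 ± 0.15, with all 3 of its probe sets below the median level, and the pseudokinase gene TRIB3 by -0.56 ± 0.06, beside the SLC7A5 given above. The other probe set of TRIB3, at a level of 5.47, was at -0.16, and the probe set test called TRIB3 as moving apart. Of 20 heat shock genes HSPA4L rose by 0.68 ± 0.06 and DNAJB1 changed by -0.33 ± 0.06 (2 higher and 2 lower adjusted over the list alone, list adjusted p = 0.718). Of 21 p53 targets 2 rose and 3 fell (3 and 3 adjusted over the list alone, list adjusted p = 0.981), with TIGAR at -0.66 ± 0.07, PMAIP1 at -0.51 ± 0.08, AEN at -0.34 ± 0.06 and SESN1 at 0.35 ± 0.06. TRIB3, HSPA4L and TIGAR stayed called with any 1 array left out. DNAJB1 and AEN lost the call in all 6 such fits, SESN1 in all but that without SRPIN803 replicate 2, PMAIP1 without any 1 DMSO replicate, and SLC38A2 without DMSO replicate 1 or 3 or SRPIN803 replicate 2 or 3 (adjusted p up to 0.106).

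The list of G1/S and DNA replication genes was higher by camera (median 0.18, adjusted p = 0.0343) with 0 of 27 genes called, also over the list alone. The estimated correlation between its genes was 0.661, and with it the call was lost (adjusted p = 0.988). It was also lost without DMSO replicate 2 (adjusted p = 0.196), DMSO replicate 3 (0.0995) or SRPIN803 replicate 1 (0.754). CDC45 was at 0.50 ± 0.15 and CCNE1 at -0.29 ± 0.08. Among G2/M and mitotic genes 0 of 28 were called, also over the list alone, with HMMR at 0.39 ± 0.11 and PLK1 at -0.25 ± 0.09. That list did not pass (adjusted p = 0.981), but did without SRPIN803 replicate 2 (0.0403).

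Single members rose in several developmental signalling lists. ID2 was the 1 of 23 TGF-beta and SMAD targets called, at 0.64 ± 0.13 (1 over the list alone, list adjusted p = 0.166). Among 17 YAP and TEAD targets FJX1 fell and ANKRD1 rose, at -0.59 ± 0.07 and 0.40 ± 0.08 (2 lower and 4 higher adjusted over the list alone, list adjusted p = 0.981). BMP4, at 0.44 ± 0.08, was the 1 of 17 Wnt and beta-catenin targets called (1 over the list alone, list adjusted p = 0.981, median -0.01, mean 0.02, test direction down). Of 11 Notch targets HES1 and NRARP rose, by 0.73 ± 0.12 and 0.26 ± 0.06 (2 over the list alone, list adjusted p = 0.892). Of 21 RNA decay genes and short-lived regulators BCL6, GADD45B and XRN1 rose, by 0.45 ± 0.07, 0.33 ± 0.05 and 0.29 ± 0.07 (7 over the list alone, list adjusted p = 0.101). FJX1 stayed called with any 1 array left out. HES1 and BCL6 lost the call without DMSO replicate 2 or 3, ID2 without any 1 DMSO replicate or SRPIN803 replicate 1, ANKRD1 in all such fits but that without DMSO replicate 2, GADD45B in all but that without SRPIN803 replicate 1, and BMP4, NRARP and XRN1 in all 6 (adjusted p up to 0.176).

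Markers of the cell type and of other cell types gave no called list. Of 25 retinal pigment epithelium markers 1 rose, the pigment cell regulator gene MITF, by 0.35 ± 0.07 (1 over the list alone, list adjusted p = 0.981), and it lost the call with any 1 array left out (adjusted p up to 0.101). Another MITF probe set above the median level was at 0.09 ± 0.14 (0.25 without SRPIN803 replicate 2). Of 15 photoreceptor and retinal neuron markers CNGA1 was called, at 0.62 ± 0.09, with its mean level over all arrays of 5.24 below the median of 5.26 (1 higher and 1 lower over the list alone, list adjusted p = 0.981). Of fibroblast and mesenchymal markers 0 of 14 were called, with COL1A1 at -0.42 ± 0.19 and ACTA2 at 0.17 ± 0.09. Of vascular endothelial markers 0 of 13 were called, with ERG at 0.13 ± 0.08 and PLVAP at 0.10 ± 0.07, and of leukocyte markers 0 of 12, with HLA-DRA at -0.22 ± 0.12 and NKG7 at 0.12 ± 0.07. These 3 lists also had 0 called over the list alone and an adjusted p of 0.981. The vascular endothelial and leukocyte lists had a median and mean above 0 and a test direction of down. Their named members ERG, PLVAP, HLA-DRA and NKG7 lay at mean levels of 3.62 to 4.11, below the median of 5.26, too dim to read a change.

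A further comparison, relevant to a compound known to inhibit a splicing factor kinase, asked whether probe sets of the same gene moved apart. In 186 of 5535 genes, covering 14401 probe sets, they did (916 at an unadjusted p under 0.05), with a median gap of 0.54 on the log2 scale between the probe sets furthest apart. In PNN, which encodes the splicing-associated protein pinin, the probe set at a mean level of 9.32 changed by -0.64 ± 0.08 and the other 3 by 0.03 to 0.06 (adjusted p = 1.10e-04). In the Golgi protein gene TMEM165, the probe set at a level of 6.14 changed by 0.93 ± 0.09 and the other 2 by -0.02 and -0.01 (1.15e-04). In TRNT1, which adds CCA ends to tRNA, the probe sets at 7.85 and 9.49 changed by -0.63 ± 0.08 and -0.57 ± 0.07 and the third, dimmer at 5.81, by 0.04 ± 0.07 (1.96e-04). In SERP1, the probe set at 5.86 changed by 0.54 ± 0.09 and the other 3 by -0.10 to 0.02 (1.96e-04). In PPP4R3B the changes ran from -0.38 ± 0.09 to 0.38 ± 0.07 (2.95e-04), and in GPATCH2L from -0.45 ± 0.08 to 0.41 ± 0.08 (4.13e-04). The PPP4R3B probe sets at these ends were dim, at 5.45 and 5.36, and the fall was not called over all probe sets (limma's adjusted p = 0.0718). Its probe sets at 9.11 and 9.62 changed by 0.04 and 0.18. Where these probe sets lie in the transcripts was not analysed here, so the kind of transcript difference is unknown. On simulated data 12.2% of the calls of this test were false. The count was 41, 41 and 48 without DMSO replicate 1, 2 and 3, and 290, 163 and 98 without SRPIN803 replicate 1, 2 and 3. Above the 75th percentile level, where fewer probe sets are tested, 4 of the 6 genes named here lost the call.

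**Figure D3:**
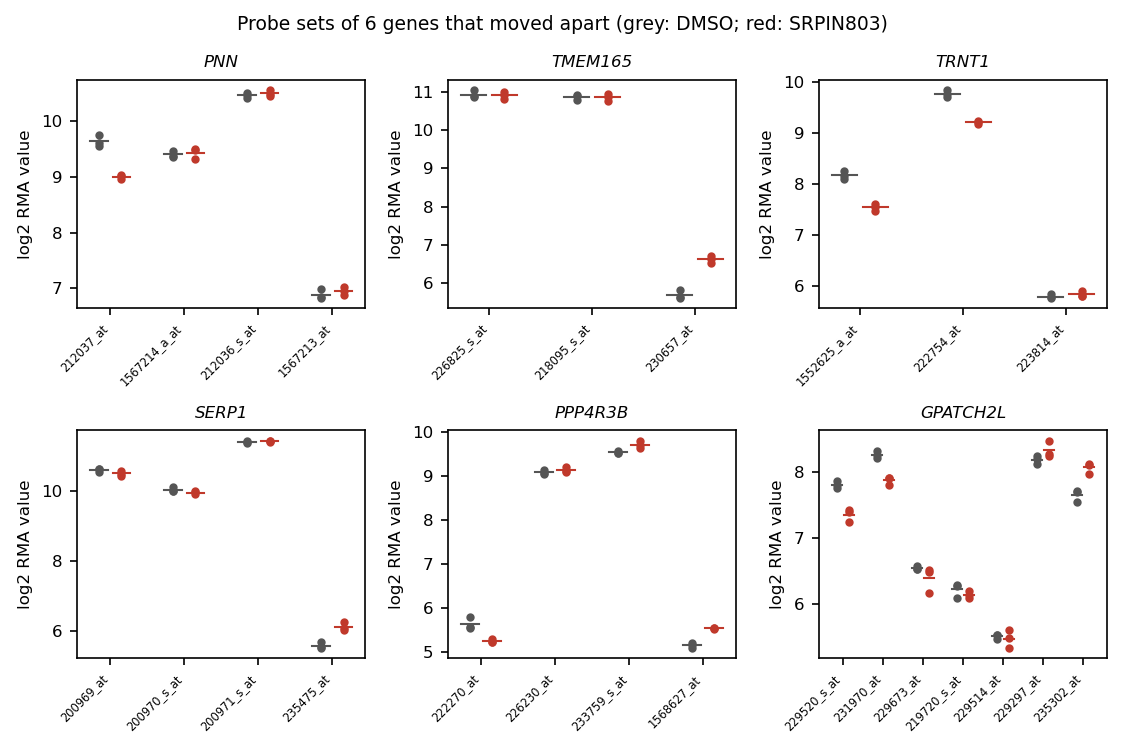
Log2 RMA values of the probe sets of the 6 genes with the smallest p in the test for probe sets moving apart, with a point per array and a bar at each group's mean (n = 3, DMSO grey, SRPIN803 red). In TMEM165 the dimmest probe set rises from 5.68 to 6.61 while the other 2 lie near 10.9 in both groups.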

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

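The tests on other splits of the arrays below were chosen after the results were seen. Probe sets outside the main comparison carried signal too. With all 54613 non-control probe sets tested by limma, 166 of the 11721 that are unnamed here were called (93 higher, 73 lower after SRPIN803), as were 48 of the 1801 that name several genes (26 higher, 22 lower). These shares, 1.42% and 2.67%, stand beside 2.43% of the probe sets naming 1 gene. They drew attention because they are differences from the solvent controls in data that the report does not use.

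The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05, so the splits cannot decide on chance. The real split, 1 of the 10, gave 1154 genes where the highest of the other splits gave 0. It gave 186 genes with probe sets apart, where the highest other gave 1, and again only 1 split, the real one, reached that count. For the gene lists at the preset correlation the real split gave 8 and the highest other 7, and with an estimated correlation 2 and 0. Every other split sets 2 arrays of a treatment and 1 of the other against the reverse, so part of any treatment effect stays in it. Each group had 3 arrays, too few to test single arrays as outliers.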

How the results depend on the processing

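VEGFA stayed lower and called under every alternative run, with log2 changes from -0.94 to -0.63. Of 73 named genes called in the main test beside VEGFA, 38 stayed called with any 1 array left out and 35 lost the call in at least 1 such fit, where fewer samples enter. The number of called genes fell to between 324 and 687 with 1 array left out. It was 1904 among genes above the median level, where fewer genes are tested, and 1965 with an intensity trend in the variance, whose cause was not tested. Stricter criteria gave 285 genes at an adjusted p under 0.01, 229 with a fold of at least 1.5 and 96 by limma's treat against a fold of 1.2. Other normalizations, probe set choices and variance models, and the actin covariate chosen after seeing the data (1073), stayed within 1.5 times the main count. That covariate had nearly equal means in both groups, so it could hardly move a difference. With VEGFA counted, 74 named genes were called, of which 16 lost the call with the replicate block and 14 with the mean of all probe sets (among them HBEGF, ABCA1, PLIN2, TEF, NR1D2 and SLC7A11). The actin covariate ended 8 calls, median centring 5, robust variance 2, and cyclic loess, quantile normalization again and an intensity trend 1 each. The share of higher genes among those called ran from 54.4% to 62.1% over samples, filters, normalizations and variance models, against 59.4%.

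Array numbers do not show a pairing. Same-numbered arrays had correlations of their deviations of 0.179, -0.0608 and 0.107, and not every array correlated best with its own number. With the replicate block 689 genes were called (424 higher, 265 lower), 638 of them among the 1154, and 122 genes had probe sets apart. The block left the 8 lists as they were.

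The lists called were 2 with an estimated correlation, 6 to 9 with 1 array left out and 11 (4 higher, 7 lower) with an intensity trend, which added the metallothionein (adjusted p = 0.0187), RNA decay (0.0316) and VEGF lists (0.0311). Fry called 8, without the unfolded protein response (adjusted p = 0.373) and G1/S lists (0.533) and with the liver X receptor (0.0158) and RNA decay lists (0.0210). Without _x_at probe sets the unfolded protein response and G1/S lists were each not called (adjusted p = 0.0662), nor was the former above the 75th percentile level (0.0545) or the latter above the median level (0.0867). The VEGF list was called with the mean of all probe sets (0.0458) and above the 75th percentile level (0.0212). Genes with probe sets apart numbered 41 to 290 with 1 array left out and 47 above the 75th percentile level, where fewer probe sets are tested. An intensity trend and array weights were not run for the probe set test, its filter at the median level is the main setting, and robust variance was not run for the lists.

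Reversed signs were in uncalled genes, and beyond the values of other probe sets given below the cause was not tested. Apart from SLC30A1 (0.14) and LIMA1 (0.26) they lay near 0 in the main test. With the mean of all probe sets SRPK1 was at -0.0625, CSNK2A1 at -0.0909, CSNK2A2 at 0.0554, SLC30A1 at -0.0225 and LIMA1 at -0.00271. Other probe sets entering that mean went down to -0.15 for SRPK1, -0.33 for CSNK2A1, -0.17 for SLC30A1 and -0.47 for LIMA1, and up to 0.13 for CSNK2A2. With median centring CSNK2B was at -0.00857 and with array weights at -0.00504. With 1 array left out SRPK1 ranged from -0.0110 to 0.0797, SRPK2 from -0.0216 to 0.0946, CSNK2A2 from -0.0570 to 0.0191 and CSNK2B from -0.0171 to 0.0251. Signal over background limits dim genes, whose RMA changes are compressed. The main probe sets of the genes with reversed signs were bright, from a level of 9.64 for SRPK2 to 11.47 for SLC30A1.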

Other observations

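These tests were chosen after the result they measure was seen: the slopes on the actin and GAPDH controls within groups, the level-matched lists for ZNF genes, the comparison of brighter with dimmer probe sets and the enrichment of SR genes. The slopes replaced 2 earlier tests of labelling, a covariate fit that could hardly move a group difference and a comparison of the control between groups that could not decide. The lists of FOXO targets and of XPO1 marker transcripts, and the gene classes below, were also made after the largest changes were seen, and genes named here fall outside the naming rule unless the report names them. Of 468 ZNF zinc finger genes 44 rose and 10 fell (9.40% and 2.14%), and of 1829 antisense, divergent and long intergenic RNA genes 89 rose and 6 fell (4.87% and 0.328%). Among all other genes 3.16% rose and 2.59% fell. ZNF682 rose by 1.24 ± 0.07, ZNF627 by 1.01 ± 0.06 and ZNF44 by 1.07 ± 0.12, and the noncoding genes RBMS3-AS3 by 1.09 ± 0.08 and DLGAP1-AS2 by 0.75 ± 0.06. Camera p was 0.00562 for ZNF genes (0.0537 with an estimated correlation) and 0.0655 for the noncoding class (0.113).

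Metallothionein and metal response genes had 0 of 13 called, also over the list alone, with SLC39A10 at 0.18 ± 0.07 and SLC30A1 at 0.14 ± 0.06 (list adjusted p = 0.105). That list passed without SRPIN803 replicate 3 (adjusted p = 0.0479) and with an intensity trend (0.0187). Of 25 proteasome subunits 0 were called, also over the list alone, with PSMD11 at -0.21 ± 0.09 and PSMB2 at 0.09 ± 0.07 (adjusted p = 0.981). Of 11 replication-dependent histone genes 0 were called, also over the list alone, with H2BC9 at 0.13 ± 0.07 and H2BC21 at -0.13 ± 0.09 (adjusted p = 0.970), and of 23 cytoskeleton and focal adhesion genes 0, with LIMA1 at 0.26 ± 0.08 and PXN at -0.10 ± 0.06 (adjusted p = 0.651).

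The first pattern is the group of 8 largest rises. A difference in 5' to 3' labelling, as the actin control reads it, stays open. At the limit of the control's 95% interval (-0.75 to 0.76), the slope within groups gave a median of 0.531% of the rise (bootstrap interval -9.35% to 12.8%). With the limit of the slope's own interval it gave at most 74.0% in any of the 8. With the GAPDH control the median was 0.290% (bootstrap interval -4.25% to 9.69%) and the most in any of the 8 was 85.9%. The 8 were picked as called genes with large rises, which are steady within groups for their rise. That favours small percents, so these slopes cannot decide. Lower AKT signalling with FOXO targets released may account for rises such as TXNIP and PDK4. Of 18 FOXO targets outside the 8 rises 4 rose and 0 fell. The 4 were SESN3, RICTOR, and SESN1 and BCL6, which are already named in the report. The median of the 18, 0.0781, had a bootstrap interval of -0.06 to 0.28 (camera p = 0.293 with an estimated correlation, 0.0409 with the preset one), which leaves it open. XPO1 inhibition is another candidate explanation, with XPO1 at 0.88 ± 0.06 and SLC43A2 at 0.98 ± 0.15, but the marker NGFR, the one not looked at before, changed by 0.0424 ± 0.089 at a DMSO level of 3.72, too dim to decide.

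The second pattern is that more ZNF genes and noncoding RNA genes were called higher than lower. A trend of change with signal level is argued against, since the medians of both classes, 0.06 and 0.04, lay at percentile 100 of 10000 level-matched lists. Signal shared between ZNF paralogs on unspecific probe sets is argued against as the whole source, since 344 ZNF genes with a plain _at probe set had a median of 0.0528 (bootstrap interval 0.03 to 0.08). Probes of plain _at sets can still share signal, and no biological explanation was tested for this pattern. The shifts are small, and as a class the noncoding genes did not pass camera at either correlation (p = 0.0655 and 0.113), the ZNF genes only at the preset one (0.00562, against 0.0537).

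The third pattern is the moving apart of probe sets. Compression of dim ones would make the brighter one move more, which held in 41.4% of the 186 genes (95% interval 34.2% to 48.8%). That argues against compression as the whole source, since the dimmer one moved more in 109 genes. Compression stays possible in the other 77, such as TXNIP. The pairs compared were picked as the furthest apart in the same data, which can move the share itself. Differences in 5' to 3' labelling stay open, since the same slope gave a median of 10.0% of the gap (5.70% with GAPDH), but genes steady within groups were picked and the slope's own interval reached 225% (261% with GAPDH), and the count was 41, 41 and 48 without DMSO replicate 1, 2 and 3, and 290 and 98 without SRPIN803 replicate 1 and 3. Changed processing of SR splicing factor transcripts may contribute, with 4 of 24 SR genes called (SRSF1, SRSF7, SRSF10 and SRSF11) against a mean of 1.18 in random lists matched on the number of probe sets (permutation p = 0.0287). That list was picked from 33 after its count was seen, its enrichment had an adjusted p of 0.128 by Fisher's exact test over those lists, YAP and TEAD targets were enriched at the same adjusted p (3 of 11), and 0 SR genes were called without DMSO replicate 1, 2 or 3 or SRPIN803 replicate 3, so it stays open.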
